A study of Mus musculus with 6 samples.

How the data were processed

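RNA was measured by sequencing in 6 libraries from mouse bone marrow-derived macrophages, cells grown out of marrow progenitors in culture. Per the labels, the cells were wild type and total RNA was extracted with TRIzol. The labels place 3 libraries in a control group at 24 h and 3 in a group given 500 ng/ml of the chemokine CCL7 for 24 h. The extraction protocol in the labels names primary chondrocytes beside macrophages, but every library is labelled as macrophages. Nothing in the labels says whether the 3 libraries of a group came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical. The common biological coefficient of variation was 6.81%.

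The deposited table holds 25711 Ensembl gene entries with a raw count and an FPKM value for each library. Whole-number counts per gene were deposited without normalization, as read from the column names and the values. FPKM as deposited by the authors is the count per kilobase of gene, scaled by the total count of the library: count divided by FPKM and by the column total gave 1 length per gene, with a largest relative spread of 9.14e-15 between libraries. These implied lengths equalled the summed exon length of GENCODE M21 (mouse genome GRCm38) for 24793 of the 25247 entries found in that annotation, which is 98.2%. Per the submitters' processing notes, Bowtie 0.12.2 and the builds mm8 and mm9 were named, with no role for each. The counting program, its strand setting and the annotation are not given in the sources used here. Coordinates are therefore given only from GENCODE M21, matched by gene identifier. Among counts below 10, even numbers were in excess (66.0% of values from 1 to 9, against 50.1% of values of 100 or more), and the value 2 was 2.47 times as frequent as the value 1. An alternative with counts divided by 2 and rounded up was therefore added. There were 175 entries without a symbol. They held 0.0019% to 0.0029% of a library's counts and were kept under their identifiers. Another 25 symbols stood on several entries, which were kept as deposited.

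Totals ran from 34860523 to 51161400 counts per library. Where all 3 libraries of a group had 0 counts of a gene, the group was set to a floor of 3 counts per library and the fold is given as a bound. Other genes with few counts keep edgeR's fitted value or, with 1 to 3 counts in a group, a ratio with a counting interval. Intervals and floors cover counting error only. If both mates of a pair were counted, counts are not independent, and the intervals are too narrow and the bounds too far from 1.

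Before the data were examined, the groups, the gene lists, the rule for named genes, the tests and most alternatives were fixed. A test with limma on log2(FPKM + 1) had been written for a table of FPKM values alone, with edgeR in its place should the table hold counts. The table did, so edgeR's quasi-likelihood test (version 4.0.16, glmQLFit and glmQLFTest, TMM scaling, group as the only term, 2-sided) was run on the counts of the 11143 genes with a mean FPKM of at least 1 over the 6 libraries. Benjamini-Hochberg adjustment was made over those genes, with a threshold of 0.05. Genes named by rule but below that mean were taken from a fit without the filter, with its own adjustment. Log2 changes are edgeR's, with CCL7 over control. Their standard errors (SE) come from the SDs of log2 CPM (TMM-scaled counts scaled by library total) in the 3 libraries of each group, and levels are CPM as mean ± SD.

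Gene lists with at least 3 tested members were compared with all other genes by camera in limma 3.58.1, on log2(FPKM + 1) with a preset correlation between genes of 0.01, then with an estimated correlation, and by fry, which asks whether a list's genes move on balance one way. Adjustment was made over the 26 lists tested. Counts of members past the threshold are given over all genes and adjusted over the list alone. The lists were the pro-inflammatory (M1) and alternative (M2) lists, CCL7 receptors, chemokines, NF-kB targets, genes strongly induced by Toll-like receptor ligands, type I interferon response, MHC class II, JAK-STAT, glycolysis, oxidative phosphorylation, cell cycle, lysosome, cholesterol, lipid handling, osteoclast, matrix proteases, NRF2 targets, unfolded protein and integrated stress response, immediate early genes, markers of macrophages, monocytes, neutrophils, dendritic cells, lymphocytes, stromal cells, chondrocytes, erythroid cells, endothelium and mast cells, X-inactivation and Y-linked genes, and mitochondrially encoded, ribosomal protein and histone genes. Some genes stand on several lists: Fcgr1, Socs3, Egr2, Klf4, Ier3, Mmp9 and Mmp8 are each on 2 of them. A polarization score per library, the mean log2(FPKM + 1) of the M1 list minus that of the M2 list, was compared by an exact 2-sided permutation test over the 20 assignments of the libraries.

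The named genes were Ccl7, its receptors and 10 polarization genes in any case. Results of some genes are not reported here. The rule added the 10 largest rises and the 10 largest falls among changed genes with no overlap between groups, without predicted genes and pseudogenes. It also added, for each list, up to 2 members that rose and up to 2 that fell with the smallest p. Where a count of members is 5 or fewer, other members are named too, and these were chosen after their values were seen.

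On simulated counts for the 11143 genes, with 50 genes changed at each of 4 fold sizes, edgeR recovered 27 at 1.25-fold, 40 at 1.5-fold, 49 at 2-fold and 50 at 4-fold, with 18 false calls among 184. The limma test recovered 17, 39, 48 and 50, with 11 false calls among 165. On a simulated shifted list camera made its call, and on 50 simulated lists with no shift it made 0. The simulated genes were drawn independently of each other. These runs therefore cannot show how calls with the preset correlation hold for lists whose genes vary together. Far fewer genes changed in them than the 69.1% called in the data. They thus cannot show how the scaling or the share of false calls behaves when most genes change.

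Alternatives changed the pseudocount, the filter, the scaling (median-of-ratios size factors, quantile normalization, TPM), the variance model, the replicate block, the gene types, the threshold, the correlation between genes, the summary of the polarization score and the libraries, leaving out each in turn. Chosen after seeing the data were limma on log2(FPKM + 1), DESeq2 1.42.0, the deposited library totals without TMM, the divided counts and edgeR's own expression filter. R 4.3.3 and Python 3.11.15 with matplotlib 3.10.9 were used. Reads shared between near-identical copies (Ly6i and its neighbours, Saa3, histone, ribosomal protein, guanylate-binding protein and Schlafen genes, T cell receptor segments) may have been split in counting, and so may those of overlapping or antisense genes, so their values are less certain.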

Results

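Gene expression was measured by RNA sequencing in wild-type mouse bone marrow-derived macrophages, with 3 control libraries and 3 libraries from cells given 500 ng/ml CCL7 for 24 h. CCL7 is a CC chemokine that attracts monocytes through the receptors CCR1, CCR2 and CCR3. The control libraries held 35585786, 44561204 and 34860523 counts and the CCL7 libraries 51161400, 44108480 and 43289351. On log2 CPM, Pearson's r across genes was 0.993 to 0.996 within groups and 0.880 to 0.890 between them. No pair of libraries from the same group agreed within counting noise, since chi-square per degree of freedom was 4.36 to 37.5. The first principal component separated the groups and held 94.2% of the variance. The second held 2.18% and set CCL7 replicate 2 (17.3) apart from CCL7 replicates 1 (-6.24) and 3 (-11.7), while the controls lay between -0.52 and 0.73.

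The comparison of CCL7 with control asks how CCL7 relates to macrophage polarization, a question the series raises for rheumatoid arthritis. With CCL7, Il1b, which encodes interleukin-1 beta, went from 0.192 ± 0.032 to 468 ± 51.2 CPM (mean ± SD, n = 3 per group), and Nos2, which encodes inducible nitric oxide synthase, from 0.195 ± 0.056 to 134 ± 19.2 CPM. All 28 interferon-response genes tested rose, and 27 of 28 cell cycle genes fell. Mrc1, the mannose receptor used as a marker of alternatively activated macrophages, fell from 254 ± 21.4 to 44.7 ± 9.65 CPM. Of 11143 genes tested with edgeR, 7698 (69.1%) changed, 3779 higher and 3919 lower, and 859 rose and 968 fell at least 2-fold. A further measure of size is that 4268 of the changed genes moved by less than 1.5-fold. The groups did not overlap at 8217 genes, where chance gives 10%. The share of changed genes that were higher was 49.1%, against 27.7% with the deposited library totals, which gave 2288 higher and 5965 lower and moved the median log2 change of all genes from -0.01 to -0.26. Small changes are therefore relative to the scaling, and some of the calls and directions that turn with it are named below.

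The genes around CCL7 itself moved differently. Ccl7 (ENSMUSG00000035373, chromosome 11, 82045712 to 82047525, plus strand, protein-coding) rose with a log2 change of 5.69 ± 0.34 (SE, n = 3 per group here and below), from 0.655 ± 0.198 to 34.6 ± 8.73 CPM (edgeR adjusted p = 1.28e-08). Ccr1 (ENSMUSG00000025804, chromosome 9, 123962124 to 123968692, minus strand) rose by 3.08 ± 0.07, from 16.4 ± 0.949 to 138 ± 7.67 CPM. In the fit without the expression filter Ccr2, the main monocyte chemokine receptor, fell (-1.64 ± 0.24, 193 counts in the 3 controls and 60 with CCL7). Ccr3 rose in that fit (1.09 ± 0.15, 246 and 520 counts).

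Among the polarization genes fixed beforehand, Nos2 (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254) rose by 9.42 ± 0.24 and Il1b (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139) by 11.22 ± 0.16 on the log2 scale. Tnf, which encodes tumour necrosis factor, rose by 4.15 ± 0.15, from 9.67 ± 0.692 to 171 ± 28.7 CPM. Il6 had 0 counts in the controls and 414 with CCL7, at least 44.8-fold higher when the controls are set to the floor of 3 counts per library, and it passed the threshold in the fit without the filter. The costimulatory gene Cd86 rose by 2.16 ± 0.09. Cd80, which encodes the related costimulatory ligand, rose by 0.31 ± 0.09 (edgeR adjusted p = 0.0150), but its log2 change was -0.02 with TPM scaling and the adjusted p was 0.0587 without control replicate 1. On the alternative side, Mrc1 (ENSMUSG00000026712, chromosome 2, 14229392 to 14332057) fell (-2.51 ± 0.20), and so did Il10, which encodes an anti-inflammatory cytokine (-0.85 ± 0.15, edgeR adjusted p = 0.00345). Arg1, which encodes arginase 1, rose without the filter (2.70 ± 0.31) from 25 counts to 163. Cd163, which encodes the haemoglobin scavenger receptor, was at 19.5 ± 0.702 and 20.2 ± 2.92 CPM (0.06 ± 0.13, edgeR adjusted p = 0.632).

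**Figure D1:**
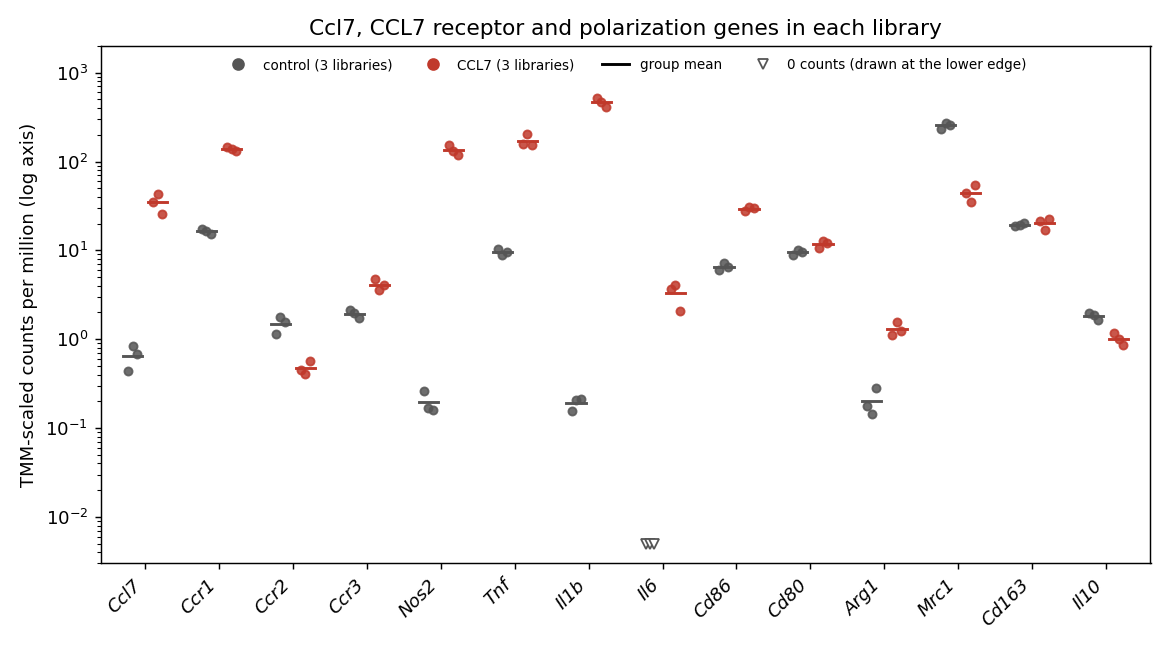
Expression of Ccl7, CCL7 receptors and polarization genes. Each point is 1 library (TMM-scaled CPM, log axis), bars are group means over 3 libraries, and open triangles at the lower edge mark 0 counts, as for Il6 in the controls. Il1b lay at 0.192 CPM in the controls and 468 CPM with CCL7, Mrc1 fell from 254 to 44.7 CPM, and Cd163 did not pass the threshold.

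All 21 genes of the pro-inflammatory (M1) list were in the data and 16 were tested. The untested members, Il6 among them, had group means of at most 3.63 CPM. Of the 16 tested genes of the list, 15 rose, 0 fell and 1, Irf5 (0.05 ± 0.05), did not pass. With the deposited totals 14 rose and 1 fell. The median log2 change was 6.12, or 5.85 with Il12a at its bound, and 3.22 on the log2(FPKM + 1) scale relative to all genes. Ptgs2, which encodes the prostaglandin-producing cyclooxygenase 2, rose by 8.48 ± 0.14. The list as a set was called higher by camera (adjusted p = 2.08e-12), but not with an estimated correlation (adjusted p = 0.105), and the adjusted p of fry was 1.62e-06. Of the 21 genes of the alternative (M2) list 20 were in the data and only 11 were tested. The untested members, Arg1 among them, had group means of at most 3.86 CPM and are left out of the values of the list. Of the 11 tested genes 4 rose, 4 fell and 3 did not pass, or 3 rose and 5 fell with the deposited totals. The scavenger receptor gene Msr1 rose by 2.64 ± 0.03, Il4ra, which encodes the interleukin-4 receptor alpha chain, by 1.15 ± 0.06, and Tgfb1 by 0.50 ± 0.07. Stab1 rose by 0.41 ± 0.12. Clec7a, which encodes the beta-glucan receptor dectin-1, fell (-1.27 ± 0.05) with Mrc1, Il10 and Folr2 (-1.02 ± 0.12), and Cd163, Egr2 (-0.21 ± 0.15) and Klf4 (0.13 ± 0.03) did not pass. Its median was 0.06, its mean -0.09 and its median -0.18 with the deposited totals, and neither camera (adjusted p = 0.673) nor fry (adjusted p = 0.0789) called a direction. The difference between the list means of tested members on log2(FPKM + 1), M1 minus M2, was -2.90 ± 0.03 (SD) in the controls and 0.63 ± 0.15 with CCL7. The gap of 3.53 had an exact permutation p of 0.1, the smallest that 3 against 3 libraries allow.

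The inflammatory and immune lists rose together, and with an estimated correlation none of them kept the call. All 15 tested genes strongly induced by Toll-like receptor ligands rose, 0 fell, with a median log2 change of 6.76 (camera adjusted p = 4.59e-17, adjusted p = 0.105 with an estimated correlation). Saa3 (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700), an acute-phase gene, rose by 10.89 ± 0.18 from 3.96 ± 0.858 to 7470.4 ± 522 CPM, and Fpr1, which encodes a receptor for formylated bacterial peptides, by 10.44 ± 0.21. All 28 type I interferon response genes rose (median 2.06, camera adjusted p = 2.24e-21, adjusted p = 0.105 with an estimated correlation), among them the nucleic acid sensor gene Zbp1 (4.85 ± 0.06) and the transcription factor gene Irf7 (4.68 ± 0.11). Of 15 chemokine genes 14 rose, including Cxcl3, which attracts neutrophils (12.05 ± 0.22), and Ccl5, which attracts T cells and monocytes (6.24 ± 0.11). The remaining member, Cxcl14, fell (-0.61 ± 0.19), and lost its call without control replicate 1 (adjusted p = 0.0717) or CCL7 replicate 1 (adjusted p = 0.0695). The chemokine median was 3.19 (camera adjusted p = 1.30e-09, adjusted p = 0.151 with an estimated correlation). Fewer chemokine genes passed with other scalings: 12 rose and 1 fell with the deposited totals, and 12 and 0 with quantile normalization.

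Of 18 NF-kB feedback and target genes 16 rose and 2 fell, with a median of 2.22 (camera adjusted p = 1.31e-11, adjusted p = 0.105 with an estimated correlation). The mitochondrial superoxide dismutase gene Sod2 rose by 4.62 ± 0.06 and Tnfaip3, which encodes the NF-kB inhibitor A20, by 3.30 ± 0.06. The falls were Cd83, a marker of mature dendritic cells (-3.35 ± 0.10), and Rel, which encodes an NF-kB subunit (-0.29 ± 0.08). Of 9 genes of antigen presentation by MHC class II, 7 rose and 2 fell, with a median of 0.94 (camera adjusted p = 0.00181, adjusted p = 0.193 with an estimated correlation). The deposited totals gave 6 rises and 3 falls, and quantile normalization 6 and 2. The class II chain genes H2-Ab1 (2.84 ± 0.05) and H2-Aa (1.85 ± 0.04) rose, while Ciita, which encodes the class II transactivator, fell (-0.63 ± 0.11) with Ifi30, which encodes a lysosomal thiol reductase (-0.33 ± 0.06). The JAK-STAT list had 19 tested genes, of which 14 rose, 3 fell and 2 (Ifngr1, 0.11 ± 0.02, and Stat5b, -0.08 ± 0.08) did not pass. Socs3, a feedback inhibitor of cytokine signalling, rose by 6.35 ± 0.20 and the kinase gene Jak2 by 2.17 ± 0.04, whereas the interleukin-6 receptor genes Il6ra (-1.21 ± 0.10) and Il6st (-0.86 ± 0.10) fell with Stat5a (-0.31 ± 0.04). The JAK-STAT median was 0.46 (camera adjusted p = 6.56e-04, adjusted p = 0.151 with an estimated correlation), against 0.22 with the deposited totals, where 11 rose and 5 fell, and 12 rose and 5 fell with quantile normalization.

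Genes of energy metabolism and stress responses mostly rose. In the list of glycolysis and HIF targets 17 of 20 rose, 0 fell and 3 (Pdk1, -0.04 ± 0.07, Pfkp, 0.02 ± 0.02, and Vegfa, 0.18 ± 0.11) did not pass, with a median of 0.96 (camera adjusted p = 1.30e-09, adjusted p = 0.105 with an estimated correlation). Scaled by the deposited totals, 17 rose and 2 fell. Pfkfb3, which encodes an activator of glycolytic flux, rose by 2.34 ± 0.07 and the lactate exporter gene Slc16a3 by 1.89 ± 0.06. Of 23 nuclear-encoded oxidative phosphorylation genes 19 rose, 0 fell and 4 (Ndufa4, Ndufb10, Ndufb3 and Sdha, -0.06 ± 0.02) did not pass, but 11 rose and 2 fell with the deposited totals and 11 rose and 5 fell with quantile normalization. Their median was 0.40 (camera adjusted p = 0.00212, adjusted p = 0.516 with an estimated correlation and 0.218 with quantile normalization), and the ATP synthase gene Atp5b (0.87 ± 0.04) and the cytochrome oxidase gene Cox5a (0.85 ± 0.05) were among the rises. Of 15 NRF2 targets of the oxidative stress response 14 rose, 0 fell and Gclc (0.06 ± 0.03) did not pass, with a median of 1.43 (camera adjusted p = 6.84e-10, adjusted p = 0.105 with an estimated correlation). Scaled by the deposited totals, 13 rose and 1 fell. The cystine transporter gene Slc7a11 rose by 5.80 ± 0.10 and Hmox1, which encodes haem oxygenase 1, by 2.31 ± 0.05. Of 18 genes of the unfolded protein and integrated stress response 15 rose, 1 fell and 2 (Phgdh, -0.11 ± 0.07, and Sesn2, 0.13 ± 0.06) did not pass, with a median of 0.73 (camera adjusted p = 1.31e-05, adjusted p = 0.151 with an estimated correlation). The deposited totals gave 13 rises and 2 falls, and quantile normalization 14 and 2. The chaperone genes Calr (1.33 ± 0.05) and Pdia4 (0.98 ± 0.04) rose and Psat1, an enzyme gene of serine synthesis, fell (-0.85 ± 0.05).

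Lysosome, lipid and immediate early genes went both ways, and camera called none of these lists. Of 23 lysosome genes 6 rose, 13 fell and 4 (Ctsa, Glb1, Grn and Lamp1) did not pass, against 6 and 17 with the deposited totals and 4 and 17 with quantile normalization, with a median of -0.14 (camera adjusted p = 0.254, but 0.00954 and lower with quantile normalization). The cathepsin gene Ctsz rose by 1.79 ± 0.06, while the protease gene Lgmn (-0.80 ± 0.03) and the mannosidase gene Man2b1 (-0.73 ± 0.03) fell. Of 19 genes of cholesterol synthesis and uptake 9 rose, 3 fell and 7 did not pass, but 7 rose and 8 fell with the deposited totals and 9 rose and 6 fell with quantile normalization. The median of 0.14 was -0.10 with the deposited totals (camera adjusted p = 0.227). Hsd17b7 rose (0.99 ± 0.02), and the sterol carrier gene Stard4 (-0.45 ± 0.07), Dhcr7 (-0.43 ± 0.07) and Insig1 (-0.16 ± 0.05) fell. Of 15 genes of lipid efflux, storage and uptake 6 rose and 9 fell (median -0.31, camera adjusted p = 0.991). Nr1h3, which encodes the liver X receptor alpha, rose by 1.45 ± 0.04 and the desaturase gene Scd2 by 1.41 ± 0.09, while the lipid-sensing receptor gene Trem2 (-1.56 ± 0.08) and the cholesterol exporter gene Abcg1 (-0.79 ± 0.06) fell. Of 14 immediate early genes 6 rose, 4 fell and 4 (Egr2, Jun, Klf4 and Klf6) did not pass, but 6 rose and 7 fell with the deposited totals and 7 rose and 6 fell with quantile normalization. Their median of 0.06 was -0.18 with the deposited totals (camera adjusted p = 0.227). Egr1 (4.74 ± 0.27) and Ier3 (3.91 ± 0.11) rose, and Atf3 (-1.07 ± 0.09), Klf2 (-0.72 ± 0.06), Btg2 (-0.20 ± 0.03) and Zfp36 (-0.24 ± 0.07) fell.

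Genes of bone and matrix breakdown, processes damaged joints are known for, were partly higher. Of 9 osteoclast genes 6 rose and 3 fell, with a median of 0.51. The camera call (adjusted p = 0.0371) was lost with an estimated correlation (adjusted p = 0.157), with size factors (0.321), with quantile normalization (0.218) and without CCL7 replicate 1 (0.0511). Mmp9, a gelatinase gene, rose by 6.52 ± 0.39 and the tyrosine kinase gene Src by 2.49 ± 0.05. The integrin beta 3 gene Itgb3 (-2.20 ± 0.08), the proton pump subunit gene Atp6v0d2 (-1.88 ± 0.06) and Nfatc1, which encodes the transcription factor that drives osteoclast formation (-0.80 ± 0.08), fell. Of 11 matrix proteases and inhibitors 9 rose, 1 fell and Plau (0.22 ± 0.17) did not pass, with a median of 0.94 (camera adjusted p = 9.79e-06, adjusted p = 0.105 with an estimated correlation). The membrane metalloprotease gene Mmp14 rose by 5.59 ± 0.09 and the collagenase gene Mmp8 by 3.91 ± 0.10, and the inhibitor gene Timp2 fell (-1.38 ± 0.05).

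Cell cycle genes fell as a group: 27 of 28 were lower and 1 was higher, with a median of -3.29 (camera adjusted p = 1.61e-10, adjusted p = 0.153 with an estimated correlation). Ccna2, which encodes cyclin A2, fell from 155 ± 2.82 to 6.92 ± 0.191 CPM (-4.48 ± 0.03) and the mitotic motor gene Kif11 from 170 ± 4.70 to 6.64 ± 0.407 CPM (-4.68 ± 0.06). The exception, E2f1 (0.15 ± 0.06, edgeR adjusted p = 0.0445), was at -0.09 with the deposited totals and its adjusted p was 0.0871, 0.183, 0.0793 and 0.0646 without control replicate 2, control replicate 3, CCL7 replicate 1 and CCL7 replicate 2. Of 56 histone genes in the list 8 were expressed enough to be tested. Of these 1 rose (H2bc4, 1.24 ± 0.06), 5 fell (H1f0, -1.16 ± 0.09, H1f2, -0.73 ± 0.07, H1f10, -1.28 ± 0.28, H2bc21, -0.53 ± 0.05, and H4c12, -1.26 ± 0.22) and 2 (H4c9, 0.32 ± 0.19, and H2bc8, 0.09 ± 0.24) did not pass. The histone median was -0.63 (camera adjusted p = 0.528).

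**Figure D2:**
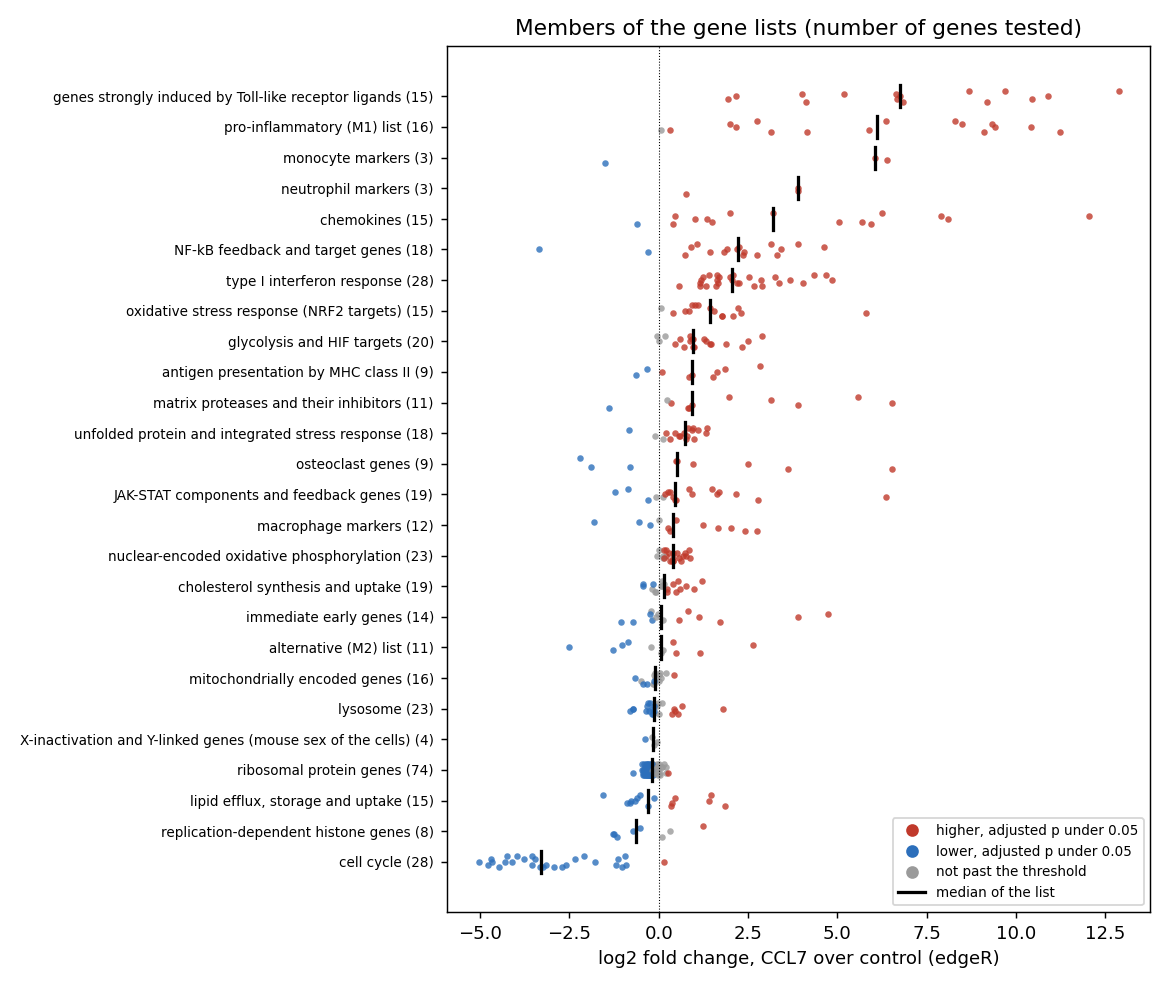
Log2 changes of the members of each gene list with at least 3 tested genes. Each point is 1 gene (edgeR log2 fold change, CCL7 over control, 3 libraries per group), red where higher and blue where lower past the adjusted threshold of 0.05, grey otherwise, and vertical bars are list medians. The list of genes strongly induced by Toll-like receptor ligands had the highest median, 6.76, and the cell cycle list the lowest, -3.29, and the medians of the cholesterol, immediate early and M2 lists turned negative with the deposited totals and that of the macrophage list with quantile normalization.

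The largest rises by the fixed rule included Lcn2, which encodes the iron-binding protein lipocalin 2 (12.87 ± 0.99, from 0.0524 ± 0.052 to 384 ± 31.3 CPM), Serpinb2, which encodes a plasminogen activator inhibitor (12.36 ± 1.05), Cxcl3, Il1b, Saa3, Fpr1 and Cd38, which encodes an NAD-consuming enzyme (10.71 ± 0.23). The size of the first 2 rests on 6 and 8 control counts and was 13.84 for Lcn2 without control replicate 1 and 13.56 for Serpinb2 without control replicate 2. Few control counts also lie behind the sizes for Cd38 (5), Cxcl3 (8) and Il1b (24). Their SEs come from the spread of 3 libraries per group and may be too small for such counts. U90926 had 0 counts in the controls and 3009 with CCL7, at least 323-fold higher, and Il12a, which encodes a subunit of interleukin-12, had 0 and 517, at least 55.7-fold higher. Ly6i, a member of the Ly6 surface protein family whose close paralogs may share reads, had 1 control count and 6512 with CCL7, a ratio of 6373 with a 95% counting interval from 1143 to 251747. Among the largest falls, Cd34 (ENSMUSG00000016494, chromosome 1, 194938819 to 194961279), a marker of haematopoietic progenitors, went from 26.2 ± 1.15 to 0.336 ± 0.191 CPM (-6.23 ± 0.51). Hpgd, which encodes the enzyme that inactivates prostaglandins, went from 134 ± 4.17 to 2.08 ± 0.654 CPM (-6.01 ± 0.26), and Gprc5c fell to a like degree (-6.19 ± 0.31). The genes Depdc1a (-5.65 ± 0.12), Cenpf (-5.31 ± 0.13), Pimreg (-5.30 ± 0.15), Depdc1b (-5.20 ± 0.30) and Aspm (-5.19 ± 0.21) fell too, with functions in cell division, and so did the helicase gene Pif1 (-5.09 ± 0.38). The T cell receptor segment Trav13-4-dv7 had 129 counts in the controls and 0 with CCL7, at least 14.1-fold lower.

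**Figure D3:**
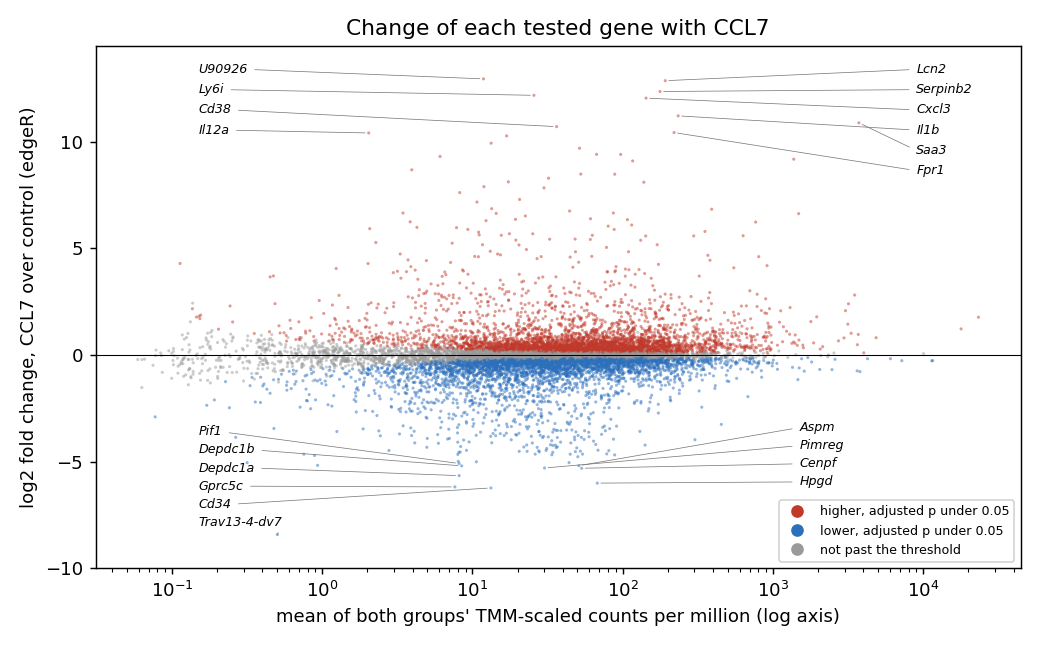
Change of each of the 11143 tested genes. The x axis is the mean of both groups in TMM-scaled CPM on a log axis and the y axis the edgeR log2 fold change, CCL7 over control; red and blue points passed the adjusted threshold of 0.05, and labels mark the 10 largest rises and 10 largest falls named by rule. The points of genes with 0 counts in a group, such as U90926 and Trav13-4-dv7, show a fitted value that is no bound.

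Markers of cell types that a marrow culture could hold were mostly low. Of 12 macrophage markers 8 rose, 3 fell and Mertk (0.00 ± 0.11) did not pass, but 6 rose and 4 fell with the deposited totals and 4 rose and 4 fell with quantile normalization. The median of 0.41 was -0.01 with quantile normalization. The camera call (adjusted p = 0.00859) was lost with an estimated correlation (adjusted p = 0.151), with size factors (0.0665) and with quantile normalization (0.910). The F4/80 gene Adgre1 rose from 1013 ± 14.4 to 5359 ± 174 CPM (2.40 ± 0.03) and the high-affinity Fc receptor gene Fcgr1 by 2.74 ± 0.06, while Cebpa (-1.80 ± 0.05) and Cd68 (-0.23 ± 0.05) fell. Of 3 tested monocyte markers Ms4a4c (6.39 ± 0.15) and Vcan (6.05 ± 0.21) rose and Cx3cr1 fell (-1.51 ± 0.17), with no call for the list (median 6.05, camera adjusted p = 0.0724, but 0.0301 and higher with TPM). The data held 9 monocyte markers, and those not tested had group means of at most 3.41 CPM. Relative to all genes the monocyte list stood at 3.42, and at 0.094 to 5.43 over the alternatives. The 3 tested neutrophil markers rose, Mmp8, S100a8 (3.90 ± 0.21) and Csf3r (0.76 ± 0.08), and the list was called (median 3.90, camera adjusted p = 0.00181, adjusted p = 0.105 with an estimated correlation). Of the 12 neutrophil markers 9 were in the data, and those not tested had group means of at most 1.27 CPM. Relative to all genes the neutrophil list stood at 3.11, and at 0.184 to 3.80 over the alternatives. The dendritic marker Itgax did not pass (-0.05 ± 0.17), the stromal marker Acta2 rose (1.99 ± 0.06, to 4.19 ± 0.295 CPM), and the endothelial markers Vwf (from 109 ± 2.86 to 54.4 ± 8.68 CPM) and Kdr (-0.66 ± 0.10) fell. No lymphocyte, chondrocyte, erythroid or mast cell marker passed the expression filter, and the highest group means among them were 3.36, 1.31, 0.203 and 12.1 CPM. The last was that of Kit, a receptor of progenitors and mast cells, in the controls, against 0.973 CPM with CCL7. Of 4 expressed X-inactivation and Y-linked genes Kdm5d fell (-0.38 ± 0.08) and Ddx3y (-0.14 ± 0.06), Eif2s3y and Uty did not pass (median -0.17, camera adjusted p = 0.240), and 4 fell with the deposited totals.

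As signs of RNA composition, mitochondrially encoded genes held 1.86 ± 0.09% (SD) of the counts in the controls and 1.56 ± 0.01% with CCL7. Of 16 tested, mt-Rnr1 rose (0.44 ± 0.12), 4 fell (mt-Cytb, -0.33 ± 0.03, mt-Nd6, -0.67 ± 0.12, mt-Nd5, -0.12 ± 0.02, and mt-Tp, -0.45 ± 0.07) and 11 did not pass, mt-Co1 among them (0.07 ± 0.05), whereas 0 rose and 10 fell with the deposited totals. The median was -0.11 (camera adjusted p = 0.227, but 0.00421 and lower with quantile normalization). Of 74 ribosomal protein genes 1 rose, 43 fell and 30 did not pass, with a median of -0.19 (camera adjusted p = 4.75e-04, adjusted p = 0.590 with an estimated correlation). With the deposited totals 0 rose and 65 fell (median -0.44), and with quantile normalization 0 rose and 67 fell (median -0.55). Rpl3 (-0.42 ± 0.06) and Rps7 (-0.44 ± 0.07) fell, Rpl27 did not pass (0.19 ± 0.11), and the rise of Rpl7l1 (0.26 ± 0.09) was -0.08 with TPM scaling. The ferritin gene Fth1 took 1.14 ± 0.04% of the counts in the controls and 3.31 ± 0.22% with CCL7, the lysozyme gene Lyz2 1.16 ± 0.04% and 2.30 ± 0.09%, and Saa3 0.000427 ± 0.0000926% and 0.684 ± 0.043%.

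Over the 26 lists tested, camera with its preset correlation called 15 higher and 2 lower, and 0 with an estimated correlation. Fry, which does not compare a list with other genes and was run on FPKM with the deposited totals, passed for all lists but the M2 list, oxidative phosphorylation (adjusted p = 0.0530) and cholesterol (adjusted p = 0.138). It thus called lists that camera did not: monocyte markers (1.27e-05) and immediate early genes (0.00105) higher, and lysosome (1.55e-05), histone (1.58e-04), lipid (5.43e-04), mitochondrial (8.12e-04) and X-inactivation and Y-linked genes (0.00121) lower. With the deposited totals the median of every list was below that with TMM. The counts adjusted over the list alone were the same as those over all genes, except that 15 JAK-STAT genes rose and 41 ribosomal protein genes fell.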

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

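Limma on log2(FPKM + 1), DESeq2, the deposited library totals, the divided counts and edgeR's own filter were chosen after seeing the data. The changed genes numbered 7590 with DESeq2, 7683 with size factors, 7552 with quantile normalization, 9798 without the filter, 9392 with edgeR's filter, 7276 among protein-coding genes, 7734 with divided counts and 8264 at an adjusted p under 0.1. With a 2-fold minimum 1827 changed, 859 higher and 968 lower, and 2599 were lower at a mean FPKM of at least 5, where fewer genes were tested. FPKM carry the deposited totals, so the higher and lower counts moved with the scaling: 2288 and 5965 with those totals, 2284 and 5916 with log2(FPKM + 0.1), 2298 and 5950 with log2(FPKM + 5), 2283 and 5930 without the variance trend, 2293 and 5933 with robust empirical Bayes, 2413 and 6150 with array weights, 2288 and 5936 with limma on log2(FPKM + 1), and 1863 and 6689 with TPM. Leaving out each library gave 6959 to 8044 changed genes, the most without CCL7 replicate 2.

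The samples share replicate numbers, but same-numbered samples did not deviate together (r from -0.09 to -0.03). That gave no sign of pairing, though 3 libraries per group cannot exclude it. With the replicate number as a block 7432 genes changed, 7382 of them shared with the 7698.

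The M1 minus M2 difference of 3.53 was 3.46 to 3.61 with a library left out, 5.24 with medians, 1.99 with z-scores, 4.99 and 2.21 with pseudocounts of 0.1 and 5, 2.74 without the filter, 4.60 at a mean FPKM of at least 5 and 4.41 with TPM. The pseudocount and the filter act on low genes by construction, and for the others the cause was not tested.

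With an estimated correlation, which moves no value and with which camera uses only the residual degrees of freedom, 0 of the other lists were called against 16. Relative to all genes on log2(FPKM + 1), the M1 list then stood at 3.22 (adjusted p = 0.105), Toll-like receptor ligand genes at 5.21, chemokines at 3.04, NF-kB genes at 2.12, interferon genes at 1.96, NRF2 targets at 1.32, glycolysis at 0.93, matrix proteases at 0.91, MHC class II at 0.89, the unfolded protein list at 0.67, osteoclast genes at 0.45, JAK-STAT at 0.42, oxidative phosphorylation at 0.36, ribosomal protein genes at -0.23 and cell cycle genes at -2.99. Adjusted p ran from 0.105 to 0.590 over these lists. Among lists that lost the call, matrix proteases (-0.049), neutrophil markers (-0.0015) and osteoclast genes (0.0066) had an estimated correlation below the preset 0.01. For these 3 the loss goes with the degrees of freedom, not with genes varying together. The osteoclast call also ended with size factors (0.48) and quantile normalization (0.44), and its values were 0.44 to 0.57 with a library left out, losing the call without CCL7 replicate 1. Over all alternatives the osteoclast value ran from 0.159 to 0.643. Quantile normalization ended the call of oxidative phosphorylation (0.14) and made calls for lysosome (-0.46) and mitochondrial genes (-0.41), and the cause was not tested. Monocyte markers gained a call with TPM (adjusted p = 0.0301). Robust empirical Bayes was not run for the lists, since camera does not take it.

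Small changes turned with the scaling. E2f1 was at -0.0848 and -0.0675 with pseudocounts of 0.1 and 5, -0.18 with TPM, -0.0810 without the trend, with robust empirical Bayes and with limma on log2(FPKM + 1), -0.10 with array weights and -0.0890 with the deposited totals. The value of mt-Co1, which did not pass with TMM, was -0.17 in each of these but for -0.26 with TPM and -0.18 with array weights, and -0.85 with quantile normalization. Rpl7l1 was at -0.0037 with quantile normalization, -0.0795 with TPM and -0.0297 with array weights, and Cd80 at -0.0197 with TPM. Apart from the scaling the cause was not tested. Of 2603 values of 118 named genes under the alternatives, 2499 stayed on the same side of the threshold, 33 lost the call, 50 gained it and these 21 reversed, and of 431 values of 24 other lists 406 stayed on the same side. Among the values that stayed, the sign turned only where neither setting made a call, as for Cd163, Rpl27 and the immediate early list.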

Other observations

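The gene families below, the count over splits of the libraries, the tests of a microbial ligand and of receptor expression, the exclusion of 2 histone genes and the look at progenitor markers were chosen after the results were seen.

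Further gene families moved with CCL7, and they overlap the fixed lists at Kif11, Cenpa, Slc7a2, Slc7a11 and Fcgr1. Chosen after the results were seen, these families were tested on the same data, so their camera p-values are descriptive and make no call. The p-values were adjusted over the 10 added families alone, and those of the fixed lists over more lists. An adjusted p under 0.05 with an estimated correlation therefore does not set a family apart from the fixed lists. All 10 tested guanylate-binding proteins and immunity-related GTPases, which attack intracellular pathogens, rose (median log2 change 2.40, camera adjusted p = 1.46e-08 over the 10 added families, 0.0452 with an estimated correlation), with Gbp6 at 5.62 ± 0.18 (SE, n = 3 per group) and Gbp2 at 3.70 ± 0.13. Of 7 Schlafen genes 6 rose and Slfn9 fell (-1.99 ± 0.11), with Slfn4 at 6.65 ± 0.14 and Slfn1 at 6.30 ± 0.44 (median 1.38, camera adjusted p = 2.40e-04, 0.0468 with an estimated correlation). All 7 amino acid transporters of the SLC7 family rose (median 1.07, camera adjusted p = 1.36e-05, 0.0452 with an estimated correlation), including Slc7a2, which imports arginine (12.9 ± 0.542 to 207 ± 2.75 CPM, mean ± SD). Of 41 proteasome subunit genes 39 rose, Psmd8 fell (-0.17 ± 0.05) and Psmd9 did not pass (-0.08 ± 0.07), against 33 rises and 2 falls with the deposited totals (median 0.61, camera adjusted p = 4.00e-12, 0.236 with an estimated correlation). The immunoproteasome genes Psmb10 (1.58 ± 0.08) and Psmb8 (1.56 ± 0.10) and the activator subunit Psme2 (2.10 ± 0.13) were among the rises. A further immunoproteasome gene, Psmb9, rose less (0.36 ± 0.10). Of 5 Fc gamma receptor genes, the shared chain gene Fcer1g included, 4 rose, with the inhibitory receptor gene Fcgr2b at 3.04 ± 0.03, and Fcgr3 did not pass (0.10 ± 0.03), while 1 fell with the deposited totals (median 1.48, camera adjusted p = 6.62e-04, 0.184 with an estimated correlation).

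Complement genes split: 7 of 12 rose, C3 (5.60 ± 0.14) among them, and 5 fell, including the C1q chain gene C1qb (-0.52 ± 0.04) (median 0.69, camera adjusted p = 0.0295, 0.236 with an estimated correlation). Among 9 Toll-like receptor genes 4 rose and 4 fell, with Tlr2 at 2.93 ± 0.08 and Tlr4 at -0.38 ± 0.12, and Tlr7 did not pass (0.05 ± 0.06). Their median of 0.05 was -0.19 with the deposited totals (camera adjusted p = 0.345). Of 5 clade B serpin genes 3 rose and 2 fell, Serpinb6a (-1.43 ± 0.04) and Serpinb6b (-2.40 ± 0.08) (camera adjusted p = 0.0875). All 19 centromere protein genes fell (median -2.15, camera adjusted p = 1.87e-06, 0.0452 with an estimated correlation), with Cenpf at -5.31 ± 0.13 and Cenpa at -4.77 ± 0.10. Of 23 kinesin genes 16 fell, 6 rose and Kif1b (0.12 ± 0.14) did not pass, against 1 rise with the deposited totals (median -1.32, camera adjusted p = 0.00481, 0.368 with an estimated correlation). The mitotic motors Kif23 (-4.64 ± 0.20) and Kif2c (-4.56 ± 0.11) fell.

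The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split was the 1 split with 7698 changed genes, and the highest count in the others was 0.

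The list of genes strongly induced by Toll-like receptor ligands rose with CCL7. Deeper sequencing of the CCL7 libraries and a few genes taking most of the counts were argued against, since the median log2 change was 6.79 after all libraries were thinned to the smallest total and 6.86 when scaled by the median gene without the 20 genes of highest count. Of the CCL7 receptors, Ccr1 had a control mean of 6.24 FPKM, above the bound of 1, while Ccr2 (0.245) and Ccr3 (0.653) lay below it. Signalling of CCL7 through a receptor is a candidate explanation for which a needed value is present, that of Ccr1. A microbial ligand carried in the CCL7 preparation may also raise such genes, and it cannot be told apart from the first, because the median of 6.76 that it predicts is the pattern itself and no library of cells given such a ligand was analysed here.

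The cell cycle list fell with CCL7, at a median of -3.29. Gene length and GC content as the whole cause were argued against, since the median was -3.25 with the length trend removed and -3.29 with the GC trend removed. Fewer cells in S phase may be part of the pattern, as the median of the 8 tested histone genes was -0.63, past the bound of -0.5 set before it was seen. However, H1f0 and H1f10 are expressed outside S phase and so lie outside the prediction, and the median of the other 6 was -0.22, so the explanation stays open. The test also covers few of the 56 histone genes of the list, since the rest lay below the expression filter. The progenitor markers Cd34 (26.2 to 0.336 CPM) and Kit (12.1 to 0.973 CPM) fell too, and a loss of dividing progenitors was not tested.

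CCL7 replicate 2 stood apart from CCL7 replicates 1 and 3 on the second principal component. Across 11080 genes, which are not independent replicates, Spearman's rho between its deviation and exon length was -0.44, with a median deviation of 0.12 log2 units in the quartile of shortest genes and -0.15 in that of the longest, in line with a length bias of this library. CCL7 replicates 1 and 3, which are set against a mean that holds replicate 2, had rhos of 0.43 and 0.22 with length, -0.250 and 0.126 with GC content and -0.204 and -0.285 with the response. GC content was argued against for replicate 2 by a rho of 0.0734, though replicates 1 and 3 lay further from 0. A stronger or weaker response to CCL7 stays open. The rho of 0.117 with the response of the other replicates lay between the bounds of 0.1 and 0.3 set beforehand. It was nearer to 0 than those of replicates 1 and 3. The mean of the other replicates enters the deviation and the response with opposite sign, which pulls each of these rhos below 0. The bounds made no allowance for that, so the test cannot decide.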
